A study of Mus musculus with 2 samples.

How the data were processed

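Messenger RNA levels were compared between 2 RNA-seq libraries of E14.1 cells, a line of mouse embryonic stem cells. One library came from cells carrying wild-type AHCY and the other from cells carrying T136A AHCY, in which the threonine at that position is replaced by alanine. Per the labels' protocols, RNA was taken up in Trizol, libraries were built with an Illumina TruSeq RNA kit, and an Illumina GAIIx was the sequencer. Each genotype had 1 library, so no spread between replicates could be measured, and no difference given here has a replicate check.

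The values deposited by the authors are 1 number per Ensembl mouse gene and library, for 25749 genes in the same order in both libraries, and they were read as RPKM, read numbers scaled by exon length and by the library's total. The unit is not named in the sources used here and was settled from the values. Multiplying each value by the gene's union exon length in GENCODE M21 and by 1 constant per library gave a whole number for 89.9% of the positive values in the WT library and 90.0% in the T136A library, within a tolerance of 0.01. The constants put the totals the authors divided by at 17506154 reads in the WT library and 18396840 in the T136A library. The submitters' processing notes name CASAVA 1.8 and the mm9 genome build, with no role for either. GENCODE M21 describes the GRCm38 build, so the lengths fitted gene models of another build than the one the notes name. The aligner, the counting program, and whether reads or read pairs were counted are not given in the sources used here. The column names of both libraries end in the digit 2, whose meaning is not given either. Because reads were counted without a stated rule for strand or for reads that match several places, values of near-identical genes and of overlapping genes are uncertain.

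Gene symbols were taken from the reference's table of gene names, which matched 25696 of the 25749 identifiers; the other 53 kept their identifier and had no gene length. For 9 identifiers that shared a symbol with another, the one with the higher total was used. Older symbols in the gene lists were matched through the synonyms of a RefSeq gene table, which moved Usp17lb into the 2-cell-like list. The main measure was log2 of T136A RPKM plus 1 over WT RPKM plus 1, on which changes of weakly expressed genes are understated. A gene entered counts and lists when it reached 1 RPKM in at least 1 library, which kept 12320 genes. Genes at least 2-fold apart on this log2 scale were counted in each direction. The design foresaw either raw counts or normalized values; the alternatives that need counts were therefore handled as described in the closing section. Printed folds are plain RPKM ratios without the added 1.

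For 10771 of the 12320 genes (87.4%), whole reads were recovered in both libraries, and a 95% interval of the fold was computed from them with the exact conditional binomial (Clopper-Pearson) method. Such an interval covers counting error only and compares these libraries, not the genotypes. A gene listed at 0 was set to 3 reads for a lower bound of its fold. Reads are not independent molecules, because no molecular identifiers were used.

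Before the data were examined, 28 gene lists were fixed. For each list with at least 4 members at or above 1 RPKM, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression. A list was said to stand apart when its median fell under percentile 2.5 or over percentile 97.5. These percentiles describe the pair of libraries and are not p-values. About 1.4 of the 27 lists that could be placed would stand apart by chance if lists shared no members and genes moved independently, which co-regulated genes do not. Other lists were written after the data had been seen and are used only in the closing section. The named genes were chosen by a rule fixed beforehand: Ahcy, the 12 genes with the highest and the 12 with the lowest log2 ratio among those at or above 1 RPKM (leaving out predicted genes, Rik clones, small RNA genes and histone cluster genes), up to 3 members at each end of every list, and Pou5f1, Sox2, Nanog, Klf4, Zfp42, Esrrb, Ogt and Mgea5. Atf4, Ddit3, Asns, Phgdh, Ddx4, Ddx3y, Uba1y, Uty, Usp9y, Fgf21 and Spry2 fall outside the rule and were chosen after their values were seen. The same holds for the genes that only the closing section names.

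The steps were tested on simulated data made for the T136A against WT comparison: Poisson reads for 25687 genes from their mean RPKM and the 2 depths, with 200 genes changed. Of genes raised 4-fold, 100% were counted as at least 2-fold higher, and of genes lowered to 0.25 of their level 79.6% were counted as lower. For folds of 2.5 and 0.4 the shares were 82.0% and 59.6%. Among unchanged genes, 21 were counted as higher and 26 as lower, out of 12006 simulated genes at or above 1 RPKM. The simulated reads carried counting error only, with no variation between cultures or libraries. The central 68% of unchanged genes ran from -0.08 to 0.08 in the simulation, while that of all genes ran from -0.48 to 0.44 in the data. These counts therefore give no rate of false calls for the data. Of 100 random lists of 20 unchanged genes, 7 stood apart.

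Alternatives were 4 other scalings, pseudocounts of 0.1 and 5, 3 other minimum levels, summed values for shared symbols, a count restricted to genes whose interval excludes a fold of 1, and the removal of chromosome 14 genes. The alternatives used 2000 random lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the figures; the trimmed mean and median-of-ratios scalings were written directly in numpy.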

Results

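The data describe messenger RNA of mouse E14.1 embryonic stem cells with either wild-type AHCY or the T136A form of this enzyme. AHCY hydrolyses S-adenosylhomocysteine, the product left when S-adenosylmethionine donates a methyl group, and so keeps the methionine cycle running. The threonine changed in T136A has been described as a site of O-GlcNAc attachment, and the comparison asks which transcripts differ when that residue is replaced by alanine. There was 1 library per genotype, with implied totals of 17506154 reads for WT and 18396840 reads for T136A. Every difference below therefore lacks a replicate check, and "higher" and "lower" refer to these libraries.

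Genes of the ATF4 pathway, which cells switch on when amino acids run short, were lower in the T136A library as a group. Chac1, which degrades glutathione, stood at 104 RPKM in WT and 3.92 RPKM in T136A, 26.4-fold lower (95% counting interval 22.0 to 32.0). The stress regulator Nupr1 was 22.7-fold lower (18.8 to 27.7), at 54.0 and 2.38 RPKM. In the opposite direction, Dazl, an RNA-binding protein of germ cells, stood at 1.24 RPKM in WT and 33.3 RPKM in T136A. The growth regulator Myc was 7.82-fold higher in T136A (6.39 to 9.63), and the homeobox gene Rhox5 was 9.39-fold higher (8.16 to 10.8). Transcripts of the central pluripotency factors Pou5f1, Sox2 and Nanog were within 1.5-fold of their WT level.

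Ahcy itself (ENSMUSG00000027597; GRCm38 chromosome 2, 155059310 to 155074497, minus strand in GENCODE M21) was at 52.9 RPKM in WT and 56.6 RPKM in T136A, a log2 ratio of 0.10. A single amino acid replacement need not alter the level of the transcript, and gene-level values cannot show the altered codon. The Ahcy level therefore does not check the labels, unless the line was made by knockdown or re-expression.

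Across the 12320 genes at or above 1 RPKM in at least 1 library, 386 (3.13%) were at least 2-fold higher in T136A and 382 (3.10%) at least 2-fold lower. The median log2 ratio was -0.03, the central 68% of genes ran from -0.48 to 0.44, and 78.3% of genes lay within 1.5-fold. Across genes, which are not independent replicates, the libraries had a Spearman correlation of 0.944 and a Pearson correlation of log2 values of 0.956. The counts rest strongly on the added constant: with 0.1 in place of 1 they were 723 and 727, and with 5 they were 101 and 114. With a minimum of 5 RPKM, 209 genes were higher and 264 lower.

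**Figure D1:**
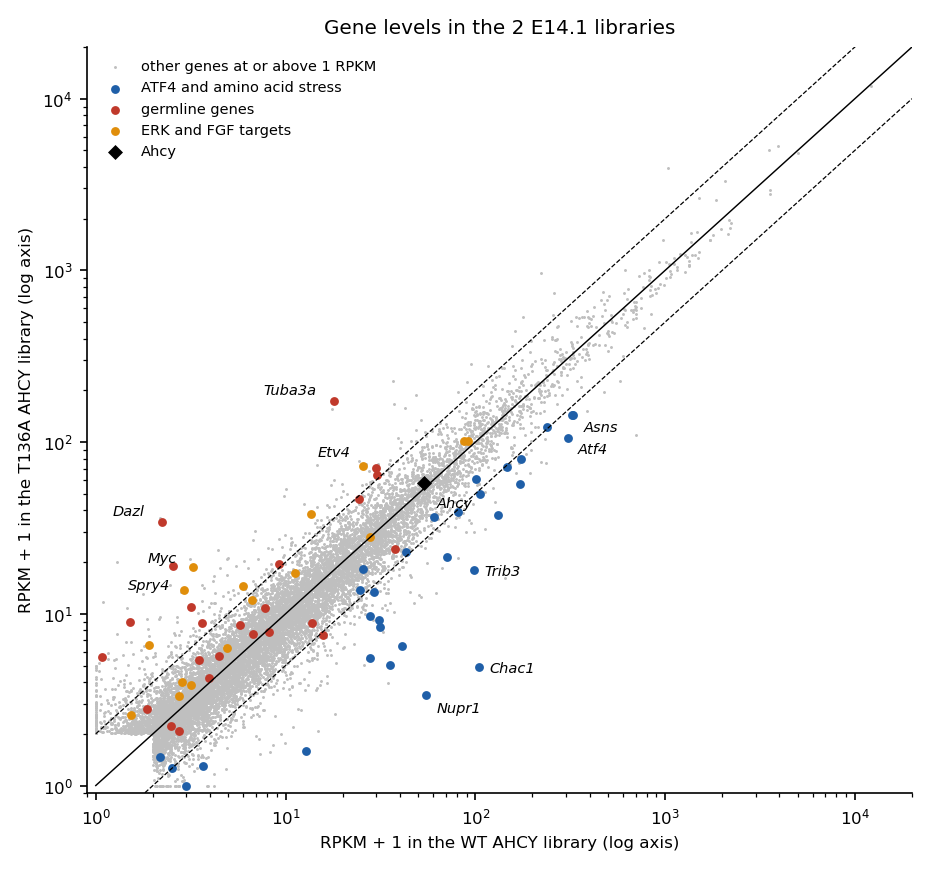
Each point is 1 of the 12320 genes, with RPKM + 1 in the WT library on the horizontal log axis and in the T136A library on the vertical log axis. The solid line marks equal values and the dashed lines 2-fold differences; all 31 ATF4 pathway genes (blue) lie below the solid line, all 16 ERK and FGF targets (orange) above it, and 10 germline genes (red) above the upper dashed line.

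The ATF4 and amino acid stress list had 31 measured members, of which 24 were at least 2-fold lower in T136A, 0 were higher, and the other 7 were also below 0. Its median log2 ratio was -1.49, at percentile 0 of random lists, and -1.35 with Fgf21, listed at 0 in T136A, set to 3 reads. Atf4, the transcription factor that drives the programme, was at 306 RPKM in WT and 105 RPKM in T136A. The related factors Atf3 (11.9 and 0.580 RPKM) and Ddit3, which encodes the death-associated factor CHOP (30.3 and 7.39 RPKM), were lower as well. The amino acid transporter Slc1a4 was 7.23-fold lower (6.51 to 8.05), and the pseudokinase Trib3 was 5.74-fold lower (5.28 to 6.24). Asparagine synthetase, Asns, stood at 327 and 142 RPKM, and the serine synthesis enzyme Phgdh at 173 and 78.9 RPKM. The smallest differences were those of the arginine transporter Slc7a3, with a log2 ratio of -0.51, of Cebpb with -0.57 and of Slc38a2 with -0.72.

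The list of the methionine cycle and one-carbon metabolism split. Of its 30 measured members, 4 were at least 2-fold lower, 1 at least 2-fold higher and 25 in between, and the median of -0.04 (percentile 40.6) did not stand apart. Lower members included Cth, which makes cysteine from cystathionine (61.4 RPKM in WT and 12.2 in T136A), and the mitochondrial folate enzymes Mthfd2 (112 and 30.0) and Shmt2 (235 and 74.9). Mat2a, the enzyme that makes S-adenosylmethionine, was at 26.6 RPKM in WT and 67.3 RPKM in T136A. Adenosine kinase, Adk, and adenosine deaminase, Ada, which remove the other product of AHCY, had log2 ratios of 0.99 and 0.72.

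Among 24 measured germline genes, 10 were at least 2-fold higher in T136A and 1, the meiotic chromosome protein Sycp3, at least 2-fold lower. The list's median of 0.60 lay at percentile 100 of random lists. Besides Dazl, the highest members were the testis tubulin Tuba3a (17.0 RPKM in WT and 172 RPKM in T136A) and Fkbp6, which acts in piRNA production and was 11.5-fold higher (8.54 to 15.7). Tuba3a and Tuba3b are near-identical copies, so their separate values are uncertain. Ddx4, a helicase of germ cells, had a log2 ratio of -0.07. On the X chromosome, 50 of 459 genes were at least 2-fold higher in T136A and 15 at least 2-fold lower. Xlr3c, of a family with near-identical copies, was 65.5-fold higher (33.0 to 153). Rhox1 was 15.6-fold higher (8.74 to 30.8), Rhox13 was 9.23-fold higher (6.44 to 13.6) and Pnma5 was 22.5-fold higher (13.7 to 39.7). Wfdc15a and the cell cycle inhibitor locus Cdkn2a completed the upper end, at 0.468 and 9.80 RPKM and at 3.41 and 22.6 RPKM.

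**Figure D2:**
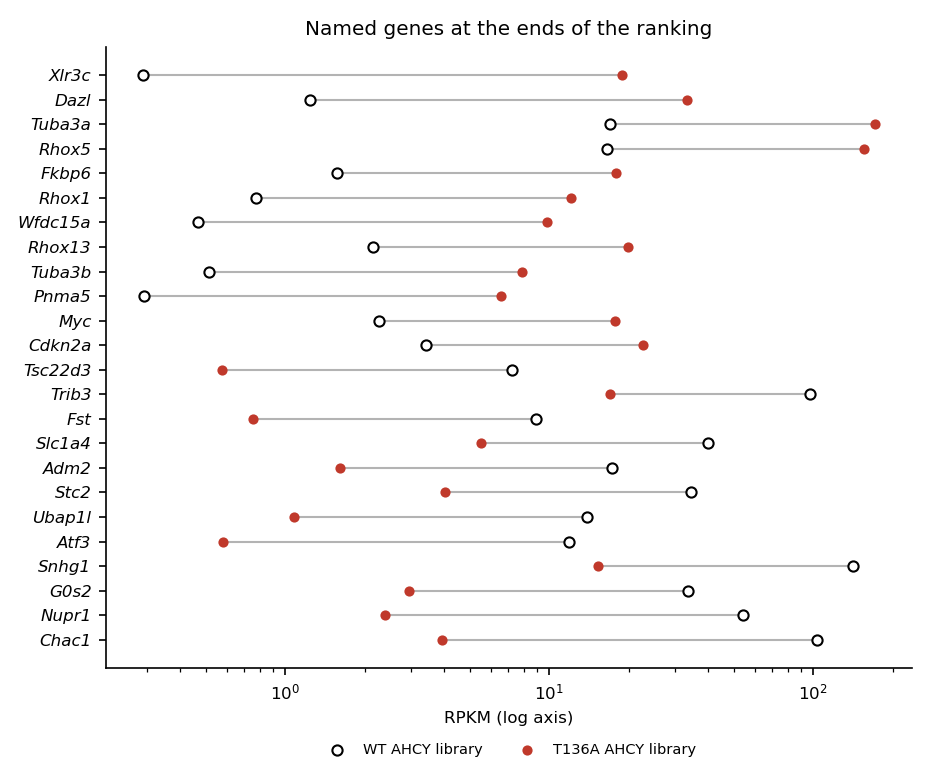
RPKM on a log axis of the 12 named genes with the highest and the 12 with the lowest log2 ratio, in the WT library (open circles) and the T136A library (filled circles). Chac1 stands at the bottom with 104 and 3.92 RPKM and Xlr3c at the top with 0.288 and 18.9 RPKM.

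Targets of ERK and FGF signalling, which moves embryonic stem cells towards differentiation, were higher in T136A: 6 of 16 measured members were at least 2-fold higher, 0 were lower, and all 16 had a log2 ratio above 0. Their median was 0.68, at percentile 100 of random lists. Besides Myc, the feedback inhibitor Spry4 stood at 1.91 RPKM in WT and 12.7 RPKM in T136A, and the immediate early gene Egr1 at 0.917 and 5.60 RPKM. The lowest ratios in the list were those of Junb (0.01), Ier2 (0.16) and Etv5 (0.23). Of 12 targets of Wnt, BMP and Nodal signals, the BMP-responsive genes Id3 (2.65 and 13.7 RPKM) and Id1 (52.9 and 92.7 RPKM) and the Wnt effector Tcf7 (22.0 and 45.2 RPKM) had the highest ratios. That list's median of 0.27 lay at percentile 97.2 and did not stand apart, although with a minimum of 5 RPKM it did, with a median of 0.59.

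Naive pluripotency genes, which mark the ground state of these cells, had a median of -0.33 at percentile 0.04. Of 26 members, 5 were at least 2-fold lower, 3 at least 2-fold higher and 18 in between, so the shift was not shared by all. Crb3 (10.8 RPKM in WT and 2.95 in T136A), the secreted protein Spp1 (477 and 195) and Prdm1 (3.97 and 1.10) were the lowest members. The imprint protector Zfp57 (38.4 and 105), Gbx2 (3.99 and 12.4) and Tex19.1 (29.0 and 70.0) were the highest. Klf4 was at 106 and 98.0 RPKM, and Esrrb at 135 and 112 RPKM.

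For the pluripotency core list the median was -0.18 at percentile 3.54, which did not stand apart. Pou5f1 was at 271 RPKM in WT and 223 RPKM in T136A, Sox2 at 343 and 294 RPKM, and Nanog at 673 and 517 RPKM. The counting intervals of the folds of Sox2 (1.13 to 1.19-fold lower) and Nanog (1.28 to 1.33-fold lower) excluded 1, which speaks of read numbers only. Zfp42, a marker of undifferentiated cells, was 1.58-fold higher. Of 27 members, 4 were at least 2-fold higher, with Dppa2 (11.6 and 42.7 RPKM), Utf1 (94.2 and 284 RPKM) and L1td1 (25.5 and 73.7 RPKM) at the top. The 3 members at least 2-fold lower were Gdf3 (84.9 and 37.8 RPKM), the adhesion protein Cdh1 (80.3 and 36.2 RPKM) and alkaline phosphatase, Alpl (67.0 and 32.8 RPKM).

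**Figure D3:**
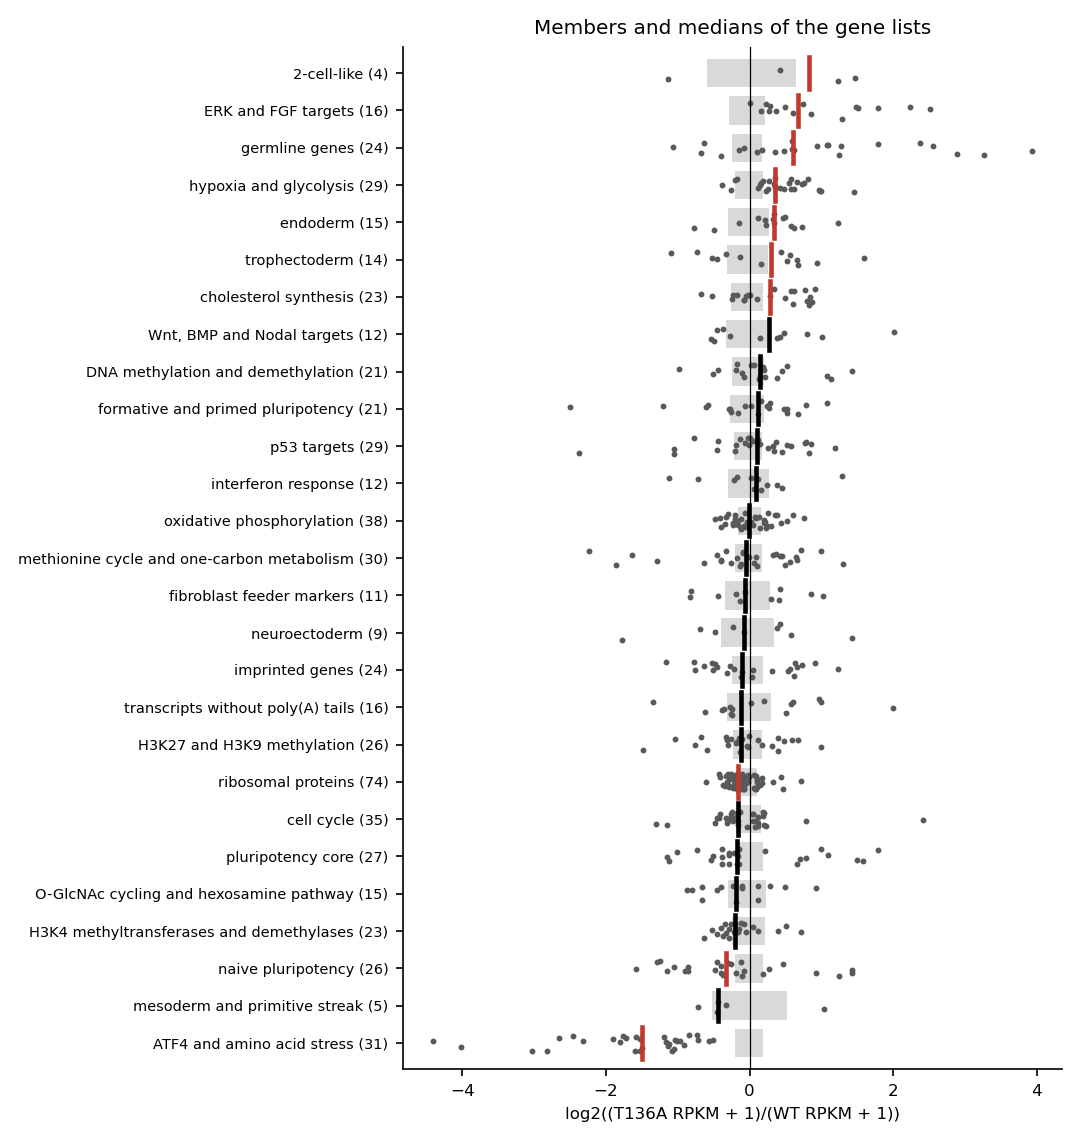
Log2 ratios of the members (points) of 27 gene lists, with the number of members in brackets, and their medians (bars, red where the list stands apart). Grey bands hold the central 95% of medians of random lists matched on mean expression; the ATF4 list has the lowest median, -1.49, and the 2-cell-like list of 4 genes the highest, 0.83.

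Markers of later fates went both ways. Formative and primed pluripotency genes had a median of 0.11 (percentile 89.4), with the activin antagonist Fst (8.91 and 0.757 RPKM) and Otx2 (13.0 and 5.06 RPKM) lower and the DNA methyltransferase Dnmt3b (3.48 and 8.45 RPKM) higher. Neuroectoderm genes had a median of -0.08 (percentile 40.7), with Sox1 at 7.77 and 1.55 RPKM. Mesoderm and primitive streak genes had a median of -0.44 over 5 members (percentile 5.09). Endoderm genes had a median of 0.34 (percentile 99.2) and trophectoderm genes one of 0.30 (percentile 98.8). Only 1 gene of each was at least 2-fold higher, the basement membrane collagen Col4a1 (3.57 and 9.80 RPKM) and Rhox6 (0.848 and 4.57 RPKM); Tfap2c, of the trophectoderm list, was at 57.7 and 26.5 RPKM. With a minimum of 5 RPKM neither list stood apart, at percentiles 94.0 and 96.3. The 2-cell-like list kept 4 of the 26 genes found and had a median of 0.83 (percentile 99.3). The 95% order-statistic interval of that median across genes was wide, from -1.13 to 1.47. Zbed3 was at least 2-fold lower (12.1 and 4.97 RPKM), and Eif1a had a log2 ratio of 0.42. Gm8300 and Usp17lb were at 0 in WT and passed the minimum through T136A alone. With Gm8300 and Usp17lb set to 3 reads the median was 0.76. Against that WT bound they were at least 19.3-fold and 12.4-fold higher in T136A, not allowing for counting error in T136A; the 95% counting intervals of the folds began at 15.3 and 9.59. Markers of fibroblast feeder cells, a possible companion of such cultures, had a median of -0.06 (percentile 44.7), with S100a6 highest (13.3 and 28.0 RPKM) and Ccn2 lowest (3.03 and 1.27 RPKM).

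Of 23 writers and erasers of histone H3 lysine 4 methylation, 0 were at least 2-fold apart on the log2 scale with 1 RPKM added. Most of them, 18, were below 0, and the median of -0.21 lay at percentile 5.32, which did not stand apart. In plain RPKM, Setd7 was 2.2-fold lower and Setd1b 2.3-fold higher, both at low levels. Setd7 (1.93 and 0.885 RPKM) and Ash2l (45.0 and 31.2 RPKM) were at the lower end and Kdm1b (2.73 and 5.16 RPKM) at the upper. Among 26 genes of lysine 27 and lysine 9 methylation the median was -0.12 (percentile 19.5), and the Polycomb cofactor Phf19 (6.72 and 1.75 RPKM) and the demethylase Kdm4a (27.9 and 13.0 RPKM) were at least 2-fold lower. DNA methylation and demethylation genes had a median of 0.14 (percentile 92.9), with Zfp57, Idh1 (44.9 and 100.1 RPKM) and Dnmt3b at least 2-fold higher. Imprinted genes had a median of -0.11 (percentile 24.6), with Grb10 (32.2 and 13.9 RPKM) lowest and Nnat (2.15 and 6.42 RPKM) highest. In the O-GlcNAc and hexosamine list, 0 of 15 genes were at least 2-fold apart and the median was -0.19 (percentile 13.1). Ogt, which attaches O-GlcNAc, had a log2 ratio of 0.29, and Mgea5, which removes it, one of -0.11.

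Genes of glycolysis and the hypoxia response had a median of 0.36 at percentile 99.98, with 25 of 29 members above 0, and lactate dehydrogenase, Ldha, at 161 RPKM in WT and 441 RPKM in T136A. Cholesterol synthesis genes had a median of 0.28 (percentile 99.7), with 0 of 23 at least 2-fold apart; Fdft1 (24.4 and 46.9 RPKM) was highest and Cyp51 (20.4 and 12.5 RPKM) lowest. Without a minimum level that list did not stand apart, at percentile 92.1. Ribosomal protein genes were slightly lower, with a median of -0.16 (percentile 0.31) and 58 of 74 below 0; many have near-identical pseudogenes that could share their reads. Oxidative phosphorylation genes had a median of -0.01 (percentile 46.1), and all 38 were within 2-fold.

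The cell cycle list had a median of -0.16 (percentile 4.12), with the inhibitor Cdkn1b at 33.5 RPKM in WT and 13.0 RPKM in T136A. For p53 targets the median was 0.10 (percentile 90.1); the stress hormone Gdf15 (log2 ratio -2.37), Pltp and Sesn2 were at least 2-fold lower and Pmaip1 (3.54 and 9.39 RPKM) higher. Sesn2 also belongs to the ATF4 list. The interferon response list had a median of 0.09 (percentile 78.6), with Bst2 (18.7 and 46.9 RPKM) higher and Ifitm3 (195 and 88.8 RPKM) lower. Transcripts without poly(A) tails, a sign of how RNA was selected, had a median of -0.11 (percentile 29.9), with the RNase P component Rpph1 at 5.73 and 25.9 RPKM. None of the 8 Y-linked genes found reached 1 RPKM in either library. Ddx3y was the highest of them in T136A, at 0.481 RPKM, and Uba1y the highest in WT, at 0.0847 RPKM. Usp9y was at 0 in both libraries, and each of the others had a higher value in T136A. Recovered reads in WT and T136A were 6 and 46 for Ddx3y, 10 and 34 for Uty, and 6 and 26 for Uba1y. The 4 chromosome Y genes outside the list that reached 1 RPKM had a median log2 ratio of -0.52. The cause was not tested.

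Of the 27 lists that could be placed, 10 stood apart, 7 on the higher side and 3 on the lower. The lower end of the ranking also held the hormone Stc2 (34.4 and 4.02 RPKM), a member of the ATF4 list. Its remaining genes were Snhg1, a host of small nucleolar RNAs (142 and 15.3 RPKM), the lipolysis inhibitor G0s2 (33.6 and 2.93) and Ubap1l (13.9 and 1.08). Adm2 (17.3 and 1.62) and the glucocorticoid-responsive gene Tsc22d3 (7.25 and 0.576) completed it. Genes of chromosome 14 were higher as a whole, with a median log2 ratio of 0.32 over 453 genes, against -0.10 to 0.02 for the other autosomes and X. Spry2, Otx2, Fdft1, Adk and Rpph1, members of the lists above, lie on that chromosome.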

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

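The removal of chromosome 14 genes and the restriction to genes whose counting interval excludes a fold of 1 were chosen after seeing the data. No alternative turned the direction of a called result. The ATF4, germline, ERK and FGF, naive pluripotency, ribosomal protein, and hypoxia and glycolysis lists stood apart on the same side in all 11 alternatives run on them, and the 2-cell-like list in 9, since it had too few members with a minimum of 5 RPKM or a mean of 1 RPKM. Medians ran from -1.60 to -1.15 for the ATF4 list, 0.35 to 1.08 for germline genes and 0.36 to 1.08 for ERK and FGF targets. With a minimum of 5 RPKM the mesoderm list and the transcripts without poly(A) tails also gave no value. The added constant moved the counts most: 723 genes were higher and 727 lower with 0.1, and 101 and 114 with 5, which also narrowed the spread of log2 ratios (the distance between percentiles 16 and 84, divided by 2) from 0.46 to 0.28 and put the cell cycle list (-0.15) below percentile 2.5. With no minimum level the spread was 0.32, the neuroectoderm list (-0.092) stood apart, and the trophectoderm (0.072) and cholesterol synthesis (0.11) lists no longer did. With a minimum of 5 RPKM, 209 genes were higher, endoderm (0.28) and trophectoderm (0.30) no longer stood apart, and Wnt, BMP and Nodal targets (0.59) did. A mean of at least 1 RPKM ended the call of trophectoderm (0.17). Quantile normalization put the pluripotency core list (-0.25) apart, and removing chromosome 14 did so for Wnt, BMP and Nodal targets (0.27). The causes were not tested. The other 318 values, of the counts, the spread, the lists and Ahcy (0.07 to 0.14), kept their side or stayed within their limit (1.5 times for counts). Single genes were run only under the 4 scalings, with 0.1 or 5 added, and with summed values for shared symbols. Of 121 other named genes, 37 crossed the 2-fold line in at least 1 of these, 29 of them falling inside it with 5 added. Under the 4 scalings only Adk and Alpl crossed. Removing chromosome 14 left 359 higher and 374 lower genes. Of the 349 higher and 339 lower genes with recovered reads, 313 and 311 had an interval that excluded a fold of 1. Thinning of reads to equal depth, an alternative meant for deposited counts, was not run, although whole reads could be recovered for 87.4% of the genes. No paired analysis was possible because each genotype had 1 library. Depth limits genes near 1 RPKM, which at an exon length of 1 kilobase is 17.5 reads in WT and 18.4 in T136A.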

Other observations

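The gene lists of this part were written after the data had been seen, and the tests on near-identical gene copies, on chaperones of the endoplasmic reticulum and on the difference in spermatid and oocyte transcripts were chosen only after their results were known. Chaperones that fold proteins in the cytosol and mitochondria were higher in the T136A library: all 18 measured members of a heat shock list had a log2 ratio above 0, 7 were at least 2-fold higher, and the median was 0.80, at percentile 100 of random lists. Hspa8, the constitutive HSP70, stood at 220 RPKM in WT and 967 RPKM in T136A, the mitochondrial chaperonin Hspd1 at 258 and 742 RPKM, and the cochaperone Dnaja1 at 16.3 and 55.2 RPKM. Among 20 genes for chaperones and folding enzymes of the endoplasmic reticulum, 16 were above 0, with a median of 0.31 (percentile 99.6). Hspa5, the main HSP70 of that compartment, was at 41.6 and 157 RPKM, and Manf at 8.27 and 26.2 RPKM, while Herpud1, which helps to clear misfolded proteins, was at 25.8 and 4.43 RPKM. Small nucleolar RNA host genes were mostly but not all lower, with a median of -0.44 over 14 genes (percentile 0.16). Of these, 10 were below 0 and 4 above. The order-statistic interval of the median across genes, from -1.04 to 0.30, included 0. The 4 genes at least 2-fold lower included Snhg12, at 36.4 and 9.26 RPKM. They also included Snhg1, already at the lower end of the ranking, so the percentile is not independent of that gene.

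Gene clusters of the X chromosome that are mainly used in reproductive tissues were mostly higher in T136A. Of 23 Rhox homeobox genes, 19 had a higher value in T136A, 1 a lower one and 3 were at 0 in both libraries, with a median log2 ratio of 0.48. The 7 that reached 1 RPKM were at least 2-fold higher, with a median of 2.32 (2.27 with genes at 0 in WT set to 3 reads), but only 3 of them reached that level in WT, so the minimum itself favoured genes higher in T136A. All 10 genes of the Xlr family were at least 2-fold higher, with a median of 2.11, or 2.10 on the same terms, and 2 of them reached 1 RPKM in WT. Xlr5a and Rhox2a were at 0 in WT, and the 95% counting intervals of their folds began at 31.8 and 15.5. Both families hold near-identical copies, so the value of a single member is uncertain. Genes of the mitochondrial genome had a median of 0.28 over 15 genes. Regulators of germ cell development went apart: Dmrt1, which holds back meiosis in the male germ line, was at 50.9 RPKM in WT and 11.6 RPKM in T136A, while Stra8, which meiosis needs, was at 3.96 and 20.1 RPKM, Rec8, a meiotic cohesin, at 8.83 and 20.9 RPKM, and Sohlh2 at 24.4 and 71.8 RPKM. The list of spermatogonium and spermatocyte transcripts they belong to had a median of -0.21 (percentile 9.22).

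Chromosome 14 carried the broadest shift of any autosome, with a median log2 ratio of 0.32 over 453 genes and 76.2% of them above 0. In 9 of its 10 windows of 10 Mb with at least 10 genes (90%), the median exceeded 0.07, the 90th percentile of 225 such windows on the other autosomes; the window at the start of the chromosome, at -0.06, did not. Random gene sets matched on GC content, gene length and expression level reached at most 0.057, which argues against those properties. A gain of chromosome 14 sequence in the T136A cells is a candidate explanation. An extra copy of the whole chromosome in every cell would add 0.58, or slightly less on the scale with 1 RPKM added. The difference from other autosomes for genes at 10 RPKM or more was 0.41, with a 95% bootstrap interval ending at 0.48. That interval came from resampling genes and does not cover variation between libraries or cultures. A gain in a part of the cells, or one partly offset in transcription, stays open, and RNA levels alone cannot show a copy number.

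The low ATF4 programme in T136A was not made by scaling, since the list's median came no closer to 0 than -1.46 under the 4 scalings tried. Random sets matched on GC content, gene length and expression level went no lower than -0.36. Chaperones of the endoplasmic reticulum had a median of 0.31, so they were not lower as a group. Because this test was chosen after its result was known, it cannot decide on a weaker unfolded protein response. Herpud1 of the same list was lower, however (25.8 and 4.43 RPKM). The list cannot judge a part of that response that leaves these chaperones unchanged, so a weakening of such a part stays open. Amino acid supply, medium age and cell density also act on the ATF4 genes. Culture or handling of the 2 samples therefore cannot be told apart from the genotype with 1 library per genotype. An effect of T136A on amino acid or methionine metabolism may underlie the difference and was not tested.

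Higher germline genes in T136A could come from germ cells or their RNA in that sample. For spermatids and oocytes, the test set beforehand did not decide. The summed RPKM of 10 transcripts in T136A was 4.46, or 13.4% of the Dazl level. A value under 10% would have argued against these cells. The sum was 4.10 in WT, so it differed by 0.37 where Dazl differed by 32.1 RPKM. That comparison was chosen after its result was known and cannot settle the question. Prm2 and Odf1 were at 0 and Zp3 was lower (3.02 and 1.40 RPKM). Ldhc (0.723 and 2.51 RPKM) and Gdf9 (0.141 and 0.428 RPKM) were higher. For spermatogonia and spermatocytes, 24 transcripts outside the germline list had a median difference of -0.40 RPKM (95% order-statistic interval across transcripts -0.96 to 0.07), and 13 stood under 0.1 of the Dazl level in T136A; yet Sohlh2, Stra8 and Rec8 were higher by 47.4, 16.1 and 12.1 RPKM, so an early germ cell with these and few of the others stays open. Without Tuba3a, Tuba3b and Xlr3a, which have near-identical copies, the list's median was 0.59, and sets matched on GC content, gene length and expression level reached at most 0.44. Activation of these genes within the stem cells themselves, for example through less DNA methylation, remains a hypothesis that expression values cannot test.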
